A study of Homo sapiens with 75 samples.

How the data were processed

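RNA of 75 cultures or aliquots was measured on as many single-sample oligonucleotide arrays with 54675 probe sets. There were 25 groups of 3 arrays, 5 groups in each of 5 human cell lines: untreated at 0 h, 3 h and 6 h, and irradiated with 5 Gy and collected at 3 h and 6 h. Per the labels, total RNA was copied into biotin-labelled cRNA, and untreated cells were mock-irradiated. The deposited values are on the log2 scale and were summarised and normalized with RMA per the submitters' processing notes. The RMA version, and whether the 75 arrays were normalized together or line by line, is not given in the sources used here. No background or presence call was used here. Values ranged from 1.64 to 13.99 log2, 0 pairs of arrays were identical, and every array was used in the group its label gives.

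Probe sets were joined to gene symbols through the table of probes and genes that came with the reference files. Of the probe sets, 41097 had 1 symbol, 1801 had several and 11777 were unnamed here. The last 2 kinds were left out, since a value for several genes cannot be given to 1 of them. Symbols were updated through gene identifiers (41043 matched, 0 changed). For each of 19775 genes the probe set with the highest mean over the 75 arrays was used, because 10523 genes had more than 1. In each line, genes were kept whose mean over its 15 arrays was above the 40th percentile of all probe sets: 14487 in G361, 14369 in HepG2, 14227 in TK6, 14654 in U2OS and 14467 in BJ.

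For each line a linear model with 5 group means was fitted to its 15 arrays (10 residual degrees of freedom) in R 4.3.3 with limma 3.58.1, with moderated variances that follow the mean level (eBayes with trend), and p-values were adjusted by Benjamini-Hochberg over the genes tested. A gene was called at an adjusted p under 0.05, and rose or fell means called higher or lower. The contrasts were irradiated against untreated at the same time, untreated at 3 h or 6 h against untreated at 0 h, and the irradiation effect at 6 h minus that at 3 h. Each fold change rests on 3 arrays against 3. Differences between lines were tested with 1 fit of all 75 arrays and a moderated F over the 4 differences of the irradiation effect, for 16027 genes past the level filter in at least 1 line. The effect of a line was also set against the mean effect of the other 4 lines. Across lines, genes called in the same direction were counted beside the number that independent lists of the same sizes would share.

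The 11 gene lists, the marker lists of the 5 lines, the tests and most alternatives were chosen before the data were examined. The lists were written from general knowledge and hold, as measured and total members, p53 targets (45 of 48), G2 and mitosis (40 of 40), DNA replication and S phase (38 of 39), replication-dependent histones (30 of 47), NF-kB targets (27 of 30), interferon-stimulated genes (31 of 33), immediate early genes (24 of 25), double-strand break repair (34 of 40), cholesterol synthesis (17 of 23), the unfolded protein and integrated stress response (24 of 24) and heat shock (15 of 18). Members without a value here were not analysed. Lists were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over 110 tests (11 lists in 10 comparisons), and the untreated contrasts and the time differences were adjusted as families of their own. Members were also tested with the adjustment over the list alone. The mean level of the p53 targets was compared between 3 and 3 arrays by a two-sided exact permutation test, whose smallest p is 0.1.

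Genes were named by a rule. Per line and time these were the 8 called genes with the largest rise and the 8 with the largest fall for which all 3 irradiated arrays lay on the same side of all 3 untreated ones. By chance alone 10% of genes have such groups. Per list they were at most 4 called members with the smallest adjusted p, and members given to show a value that was not called. The rule also named genes called the same way in all 5 lines (up to 20), the 10 genes with the smallest adjusted p in the F test, and in the untreated controls the 4 largest rises and 4 largest falls per line at 6 h. Genes outside it are said to be chosen after their values were seen.

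Replicate numbers occur in every group, so it was checked whether they pair the arrays. After the group means were removed, arrays with the same number were correlated, and numbers counted as pairing where the lowest of the 3 correlations was at least 0.1. This held for all comparisons of irradiated with untreated arrays except HepG2 at 3 h (lowest 0.0962) and BJ at 6 h (-0.0306). Where it held for irradiated against untreated arrays, counts with the replicate number as a block are given beside the others.

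The alternatives were no level filter, quantile normalization of the 15 arrays of a line, the mean of all probe sets of a gene, 1 fit of all 75 arrays, a fit of the 6 compared arrays alone, the replicate number as a block, camera with the correlation estimated (statmod 1.5.0 installed), fry, and each array left out in turn. After the data were seen, 2 were added: untreated 0 h arrays as the control, and all arrays of 1 replicate number left out. The methods were tested on simulated data with the spread of each line, in which 200 genes were changed. Values were drawn independently for each gene and array, without the correlation found between real arrays of the same replicate number. The shares that follow may therefore differ in the real data. A change of 2 log2 was recovered in 95.4% to 100% of genes, of 1 log2 in 59.7% to 91.0% and of 0.5 log2 in 1.49% to 41.8%, and at most 10.9% of the calls were false. In the F test the share was 75.7% at 1 log2, with 15.7% of its calls false, above the nominal 5%. Of the other probe sets of called genes, 43 of 543 went the opposite way in TK6 at 3 h, 103 of 945 in TK6 at 6 h, 1 of 47 in BJ at 6 h and 0 in the other comparisons.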

Results

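Messenger RNA levels were measured on 75 single-sample arrays from 5 human cell lines, named here as labelled. The names stand for the melanoma line G361, the hepatoma line HepG2, the B lymphoblastoid line TK6, the osteosarcoma line U2OS and the skin fibroblasts BJ. In each line, 3 arrays each came from cells 3 h and 6 h after 5 Gy of ionising radiation, and 3 each from mock-irradiated (untreated) cells at 0 h, 3 h and 6 h. The design asked how each line's transcripts changed after irradiation relative to untreated cells of the same time. Array medians lay between 3.91 and 4.07 log2 and upper quartiles between 5.88 and 6.41. Both the lowest upper quartile and the lowest 95th percentile, 8.94, belonged to replicate 1 of untreated U2OS at 3 h. Arrays of a group correlated at 0.970 to 0.996, and arrays of different lines at no more than 0.932. The 5' minus 3' difference of the GAPDH control was -0.94 to -0.68 in the 5 replicate 1 arrays of G361 and at or above -0.18 in every other array. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical, and 3 arrays per group limit the precision.

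Markers of each line's tissue were examined first. All 8 measured melanocyte markers were highest in G361, among them MLANA at 12.45 log2, PMEL, a melanosome protein, at 12.85 and TYR, the tyrosinase of melanin synthesis, at 11.87. All 11 B lymphoid markers were highest in TK6 (CD79A, a part of the B cell receptor, at 9.46 and CD74 at 12.19, but PAX5 at 4.96 against 4.82 in G361 and BLK at 3.65 against 3.40 in U2OS) and all 12 fibroblast markers in BJ (COL1A1 at 12.92, LUM at 11.76). Of 8 osteoblast markers, 3 were highest in U2OS, with SPP1 (osteopontin) at 8.84 and RUNX2, an osteoblast transcription factor, at 8.04 against 9.17 in the arrays labelled HepG2. Of 11 hepatocyte markers, only AFP (alpha-fetoprotein) was highest in the arrays labelled HepG2, at 5.89 against 5.48 in U2OS. Albumin (ALB) was at 2.77 there and the apolipoprotein APOA1 at 4.07, and the mean of the 11 markers was 3.75, below the highest array of the other lines at 4.39. The protease inhibitor SERPINA1 was at 3.26 there and at 8.57 in U2OS. Of the fibroblast markers, the collagen gene COL6A3 stood at 11.30 in the arrays labelled HepG2 (12.06 in BJ, 3.12 in G361) and the transcription factor gene TWIST2 at 7.75 (10.43 in BJ, 3.36 in G361), while COL1A2 was at 3.99.

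**Figure D1:**
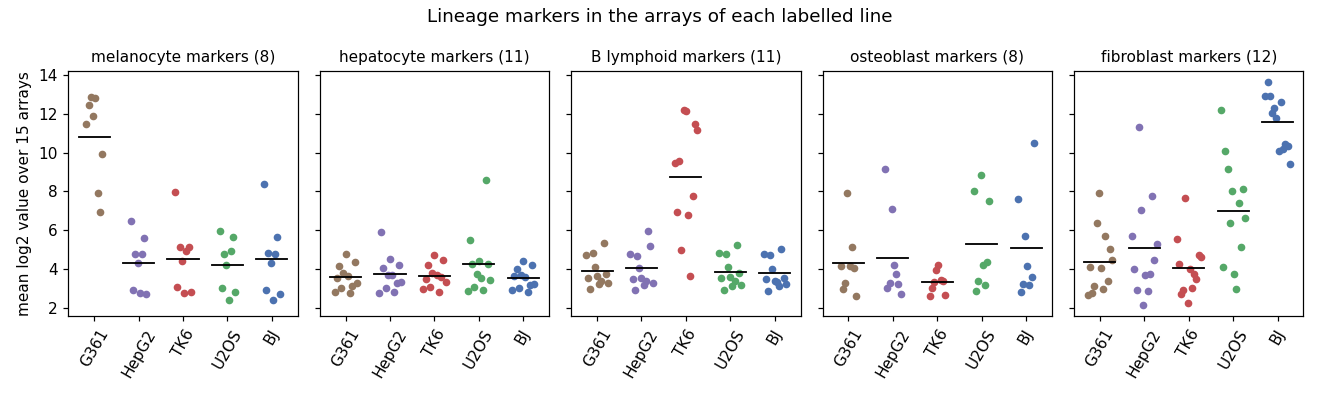
Mean log2 value over the 15 arrays of each labelled line (vertical axis), 1 point per marker gene and a line at the mean of the list, with 1 panel per marker list. The melanocyte, B lymphoid and fibroblast lists stood apart in G361, TK6 and BJ, with means of 10.79, 8.73 and 11.55, while the hepatocyte list had a mean of 3.75 in the arrays labelled HepG2.

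The mean log2 level of 45 p53 target genes gave 1 value per array. Relative to the mean of the line's 0 h arrays, the irradiated arrays of TK6 stood at 1.02 to 1.26, those of U2OS at 0.40 to 1.18 and those of BJ at 0.37 to 0.47. No untreated array of these lines at 3 h or 6 h was above 0.154. Arrays labelled untreated at 6 h stood at 0.56 to 0.61 in HepG2 and at 0.55, 0.56 and 0.04 in G361, and replicate 3 labelled untreated at 3 h in G361 stood at 0.52. Arrays labelled irradiated at 3 h stood at 0.01 to 0.11 in HepG2 and at -0.02 to 0.09 in G361, while those labelled irradiated at 6 h stood at 0.71 to 0.81 and at 0.29 to 0.55. Irradiated minus untreated, the score differed at 3 h and 6 h by 1.21 and 1.29 in TK6, 0.61 and 0.91 in U2OS, 0.53 and 0.43 in BJ, -0.20 and 0.03 in G361, and -0.09 and 0.18 in HepG2. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays allow, except for 0.4 in HepG2 at 3 h and 1 in G361 at 6 h. Adjusted over the 10 comparisons, the lowest exact p was 0.125. G361 and HepG2 are therefore described by what their arrays are labelled.

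**Figure D2:**
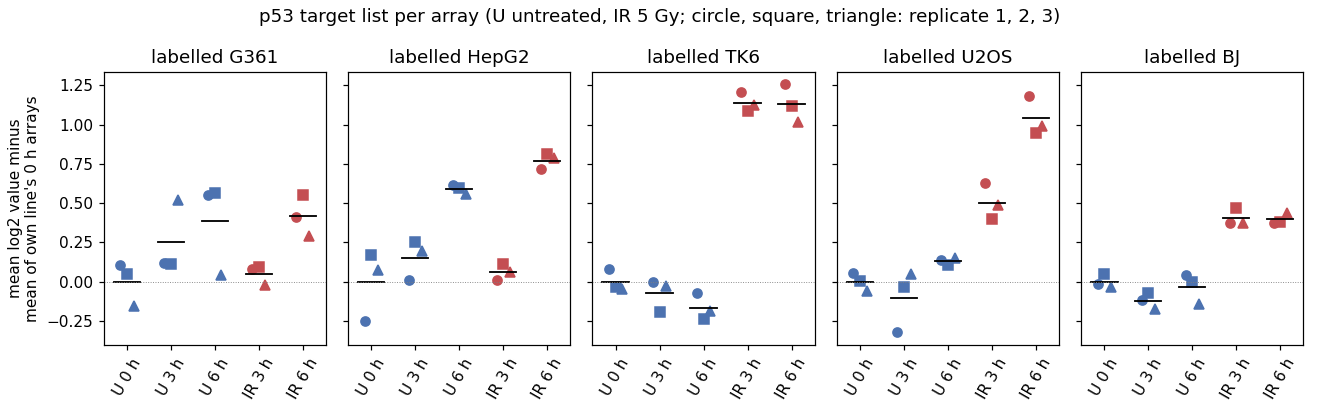
Mean log2 level of the p53 target list minus the mean of the same line's untreated 0 h arrays (vertical axis), 1 point per array, by line and by labelled treatment and time (horizontal axis). Irradiated arrays of TK6, U2OS and BJ stood at 0.37 or above and their untreated arrays at 0.154 or below. Arrays labelled untreated 6 h in HepG2 stood at 0.56 to 0.61 and those labelled irradiated 3 h at 0.01 to 0.11.

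In TK6 at 3 h, p53 targets rose together and genes of mitosis fell together. The lysosomal fucosidase gene FUCA1 rose by 3.67 log2 (SE 0.28, n = 3 arrays a group, adjusted p = 1.09e-07), a 12.7-fold increase, and CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, rose by 2.25 (SE 0.12, adjusted p = 1.29e-09). GASK1B (3.32), the p53-inducible TP53INP1 (3.14), the secreted cytokine gene GDF15 (3.02), the mTORC1 inhibitor gene SESN1 (2.67), the pseudogene ANKRD20A12P (2.32) and the noncoding RNA PURPL (2.32) were the other largest rises. The largest fall was that of PSRC1, a spindle protein gene, at -3.18 (SE 0.16, adjusted p = 1.27e-09). The kinetochore kinesin gene CENPE followed at -2.30, and then DEPDC1 at -1.76, the cohesin protector gene SGO2 at -1.74, the mitotic kinase gene AURKA at -1.71 and the mitotic kinesin genes KIF18A (-1.705), KIF14 (-1.70) and KIF20A (-1.70). Of 44 p53 targets, 35 rose (38 adjusted over the list alone), including the phosphatase gene PPM1D (1.68) and TIGAR (1.35), and 0 fell. Of 40 genes of G2 and mitosis, 32 fell (36 adjusted over the list alone) and 0 rose. The list tests gave adjusted p = 6.76e-76 and 1.54e-75, or 5.34e-04 and 7.89e-05 with an estimated correlation.

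Other groups moved in few members in TK6 at 3 h. The transcription factor genes MYC and ATF3, both immediate early genes, went opposite ways, MYC at -1.29 (SE 0.12) and ATF3 at 1.98 (SE 0.19). The double-strand break repair gene RAD51C rose by 0.91, and the replication genes GINS4, PCNA and CDC6 rose by 1.16, 0.35 and 0.435. H2AC6, a histone gene, fell by 0.71, the interferon-stimulated gene IFIT1 fell by 1.09 and the inflammatory cytokine gene TNF fell by 0.94. In cholesterol synthesis, HSD17B7 was at 0.64 and SQLE at -0.53, both called. Of the 9 lists other than p53 targets and G2 and mitosis, DNA replication was called (adjusted p = 1.57e-04, but 0.511 with an estimated correlation), and the other 8 had adjusted p of 0.297 to 0.928. In all, limma called 568 of 14227 genes, 268 higher and 300 lower, with 98 and 53 of them at least 2-fold. The replicate numbers paired the arrays, and with the replicate number as a block the count was 1203. Leaving out replicate 2 or replicate 3 of every group gave 248 and 211.

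At 6 h after irradiation, p53 targets were among the largest rises in TK6. FUCA1 was 22.9-fold higher (4.52 log2, SE 0.28, adjusted p = 1.89e-08), the quinone oxidoreductase gene TP53I3 11.3-fold (3.50, SE 0.26, adjusted p = 1.08e-07) and GASK1B 11.1-fold (3.47). TP53INP1 (3.21), GDF15 (3.16), ASTN2 (3.035), CYP4F3 (3.02) and FAM13C (2.91) came next. Untreated CYP4F3 (3.11) and FAM13C (2.84) lay below the level limit of 3.52 used for testing, so their sizes and order are uncertain, and counted from that limit they were 2.61 and 2.24. The largest falls were the serotonin receptor gene HTR6 (-1.67, SE 0.26, adjusted p = 3.6e-04), PVRIG (-1.44), SCARNA15 (-1.26), HPDL (-1.25), OPN3 (-1.25), the mRNA 3'-end cleavage factor gene PCF11 (-1.23), CDC20, an activator of the anaphase-promoting complex (-1.19, SE 0.10), and ERICH3 (-1.09). Of 44 p53 targets, 38 rose, and the same number did so adjusted over the list alone, among them TRIM22 (1.31) and the DNA damage recognition gene DDB2 (1.86). Of 40 genes of G2 and mitosis, 22 fell (26 adjusted over the list alone), including CCNB1, the gene of cyclin B1 (-0.98), and the spindle checkpoint kinase gene BUB1 (-0.79). The list tests gave adjusted p = 2.6e-68 and 6.17e-22, or 6.88e-04 and 0.00445 with an estimated correlation.

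Among 24 genes of the unfolded protein and integrated stress response, 7 rose in TK6 at 6 h, 7 adjusted over the list alone. They included CHAC1, a glutathione-degrading enzyme gene (1.72, SE 0.19), the stress transcription factor gene DDIT3 (1.10), CEBPB (1.02) and the cystine transporter gene SLC7A11 (0.71). The list had adjusted p = 0.00159, but adjusted p = 0.103 with an estimated correlation. Of 25 replication-dependent histone genes 4 fell (6 adjusted over the list alone), H2AC6 at -1.09, H2BC14 at -1.03, H2BC5 at -0.49 and H2BC12 at -0.39 (list adjusted p = 1.3e-05, and 0.142 with an estimated correlation). Immediate early genes (ATF3 at 2.20, IER5 at 0.59, IER3 at 0.42, MYC at -0.59) and heat shock genes (HSPA4L at 0.55, DNAJB1 at -0.57, BAG3 at -0.46) had called members in both directions. Their lists had adjusted p = 0.0171, higher, and 0.0175, lower, but 0.326 and 0.103 with an estimated correlation. The other 5 lists had adjusted p of 0.0743 to 0.704. Members called in them were the repair genes RAD51C (0.81) and BRIP1 (0.76), PCNA (0.47), TK1 (0.56), UHRF1 (-0.67), CCNE1 (-0.52), EBI3 (0.51), IRF1 (0.57), LTA (-0.68), IFIH1 (0.50) and HSD17B7 (0.79). The called genes numbered 887, 570 higher and 317 lower, or 1868 with the replicate number as a block. Leaving out replicate 2 or 3 of every group gave 326 and 246, and without the single arrays irradiated replicate 1, untreated replicate 2 or untreated replicate 3 the counts were 585, 548 and 537.

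The fall of mitotic genes in TK6 was smaller at 6 h than at 3 h. The test of the difference between the 2 times called 42 genes, 40 of them with the more positive change at 6 h. Of these 40, 34 were among the genes that fell at 3 h, 14 were in the list of G2 and mitosis and 0 in the list of p53 targets. The following were chosen after their values were seen. AURKA went from -1.71 to -0.31 (difference 1.40, SE 0.15, adjusted p = 9.13e-05), PSRC1 from -3.18 to -1.04, KIF18A from -1.71 to 0.10 and CENPE from -2.30 to -0.64. INHBE, an inhibin subunit gene, went from 0.01 to 1.85 and CHAC1 from 0.35 to 1.72, and the lower ones were the splicing factor gene SRSF7 (0.09 to -0.41) and the DNA methylation cofactor gene UHRF1 (0.19 to -0.67). The list of G2 and mitosis was higher in this difference (adjusted p = 2.87e-32, and 0.00347 with an estimated correlation). With the replicate number as a block the count was 146, and it fell to 17 without untreated replicate 2 at 6 h and to 19 to 27 without any of 6 other single arrays. In the other 4 lines limma called 0 genes for this difference, with 102 (G361), 329 (HepG2), 371 (U2OS) and 302 (BJ) at an unadjusted p under 0.05.

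In U2OS at 3 h GDF15 rose by 2.76 log2 (SE 0.26, adjusted p = 4.53e-05), or 2.52 counted from the level limit of 3.52, since its untreated mean of 3.27 lay below that limit. It was followed by the stress-induced transcription factor gene ATF3 (1.97), TP53INP1 (1.78), SESN1 (1.46), CDKN1A (1.33, SE 0.15), TENT5A (1.30), SESN2 (1.25) and PPM1D (1.11). FAM83D, a spindle protein gene, fell by 1.10 (SE 0.15) and BORA, an activator of Aurora A, fell by 0.93. Of 45 p53 targets 9 rose (24 adjusted over the list alone; list adjusted p = 2.83e-33, and 0.0134 with an estimated correlation). MDM2, the ubiquitin ligase gene of p53, was at 0.73 (SE 0.19) and was not called (adjusted p = 0.492). Of the genes of G2 and mitosis 1 fell (8 adjusted over the list alone), with adjusted p = 2.81e-13 for the list but 0.203 with an estimated correlation. Relative to 0 h, the mitotic score of untreated replicate 1 stood apart, at -0.46 against -0.07 (replicate 2) and -0.04 (replicate 3). NF-kB targets had a median of 0.27 with 0 members called (3 adjusted over the list alone), and their list was called higher (adjusted p = 0.0012, and 0.0316 with an estimated correlation). In all 13 genes were called, 11 higher and 2 lower, or 36 with the replicate number as a block. The median of all genes stood at 0.10 here, and after quantile normalization it was 0.01 and 28 genes were called, 13 higher and 15 lower. Without replicates 1, 2 or 3 of every group the counts were 37, 3 and 2, and 8 without irradiated replicate 1 or irradiated replicate 3.

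In U2OS at 6 h PIF1, a helicase gene, fell by 2.32 log2 (SE 0.24, adjusted p = 6.34e-05), and GAS2L3 (-1.67), EXPH5 (-1.49), PSRC1 (-1.47), the mitotic kinase gene PLK1 (-1.40), TRIM59 (-1.36), GCNT1 (-1.36) and BORA (-1.34) followed. Rises were led by GDF15 (2.81, SE 0.26, adjusted p = 3.55e-05, 6.998-fold), TP53INP1 (2.17), the stem cell factor gene KITLG (2.15), ATF3 (1.93), the death receptor gene FAS (1.86), SESN1 (1.74), ANKRD20A12P (1.68) and NECTIN4 (1.66). MDM2 was called at this time (1.47, SE 0.19). Of 45 p53 targets 21 rose (34 adjusted over the list alone; list adjusted p = 2.02e-85, and 5.34e-04 with an estimated correlation). Of 40 genes of G2 and mitosis 21 fell (35 adjusted over the list alone), including AURKA (-1.30) and KIF20A (-1.23), with adjusted p = 3e-86 for the list, and 0.00227 with an estimated correlation. The histone gene H2AC6 fell by 0.86. The 94 called genes were 45 higher and 49 lower, and 157 were called with the replicate number as a block. Leaving out replicates 1, 2 or 3 of every group gave 256, 18 and 12, and 56 to 62 were called without irradiated replicate 2 or 3 or untreated replicate 2 or 3.

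In BJ fibroblasts at 3 h every called gene rose. GDF15 led with 2.23 log2 (SE 0.15, adjusted p = 5.57e-07), a 4.68-fold increase, before LRATD2 (1.96), the death receptor gene TNFRSF10A (1.72), PPM1D (1.69, SE 0.13), SESN1 (1.48), MDM2 (1.41), CDKN1A (1.28, SE 0.10) and ATF3 (1.23). GADD45A, a growth arrest gene, rose by 0.97 and the immediate early gene IER5 by 0.67. Of 45 p53 targets 14 rose (24 adjusted over the list alone; list adjusted p = 2.02e-80, and 7.89e-05 with an estimated correlation). Among genes of G2 and mitosis 0 were called (2 adjusted over the list alone), while the list had a median of -0.41 with adjusted p = 9.73e-22, but 0.261 with an estimated correlation. Single arrays lay apart within both groups. Relative to 0 h, irradiated replicate 2 stood at -0.12 against -1.14 (replicate 1) and -0.98 (replicate 3), and untreated replicate 1 at -0.78 against 0.01 (replicate 2) and -0.21 (replicate 3). The called genes numbered 26, or 32 with the replicate number as a block. Leaving out replicates 1, 2 or 3 of every group gave 17, 13 and 12.

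In BJ at 6 h CCNE2, the gene of cyclin E2, fell by 2.35 log2 (SE 0.41, adjusted p = 0.0186), ZNF367 by 2.23 and the spindle checkpoint kinase gene TTK by 1.64, and NEK2 (-1.61), the CDK-activating phosphatase gene CDC25A (-1.55), CDCA8 (-1.52), KIF14 (-1.34) and CCNB1 (-1.28) followed. GDF15 (1.22, SE 0.15), CDKN1A (1.04, SE 0.10, adjusted p = 2.23e-04), the activin-binding follistatin gene FST (0.99), MDM2 (0.95), CYFIP2 (0.94), TIGAR (0.92), PTCHD4 (0.91) and CABYR (0.85) were the largest rises, with untreated PTCHD4 (3.33) below the level limit of 3.47, so its size and order are uncertain, and counted from that limit it was 0.77. Of 45 p53 targets 12 rose (27 adjusted over the list alone; list adjusted p = 8.16e-43, and 4.98e-04 with an estimated correlation), among them FAS (0.72). Of 40 genes of G2 and mitosis 8 fell (37 adjusted over the list alone), such as PLK1 (-1.24), PSRC1 (-1.26), HJURP (-1.27) and the centromere histone gene CENPA (-1.195), with adjusted p = 1.24e-58 but 0.0674 with an estimated correlation. DNA replication genes had a median of -0.56 with 1 called, CCNE2 (23 lower adjusted over the list alone), and adjusted p = 1.27e-26 but 0.158 with an estimated correlation. The histone gene H2AC6 rose by 0.66. There were 34 called genes, 21 higher and 13 lower. After quantile normalization there were 53, with 25 higher and 28 lower, while 1 fit of all 75 arrays called 148 with 20 higher, and the 6 compared arrays alone 105 with 22 higher. Without replicates 1, 2 or 3 of every group there were 11, 3 and 0, and without any single array of the comparison 12 to 20.

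**Figure D3:**
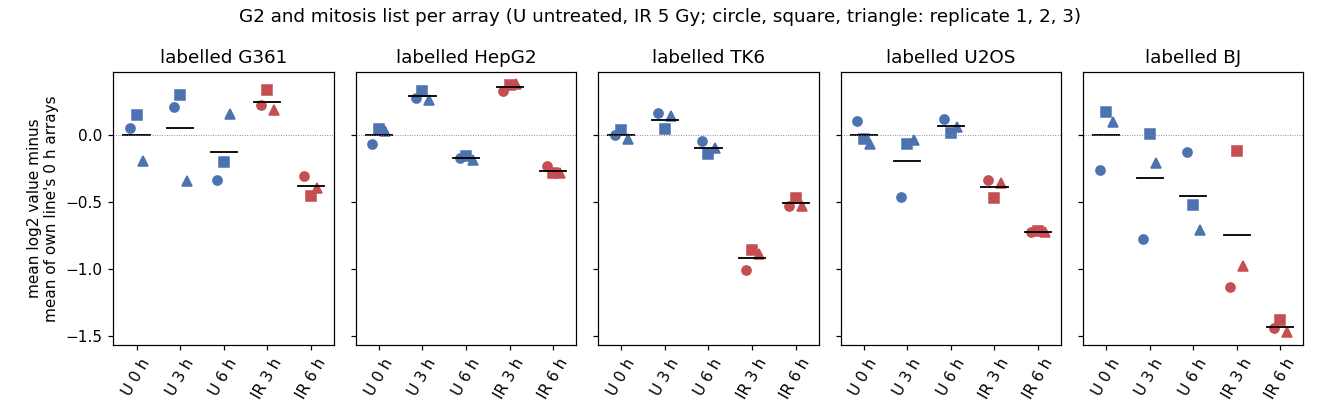
Mean log2 level of the 40 genes of G2 and mitosis minus the mean of the same line's untreated 0 h arrays (vertical axis), 1 point per array, by line and by labelled treatment and time (horizontal axis). Irradiated group means were -0.92 and -0.51 in TK6 at 3 h and 6 h, -0.39 and -0.72 in U2OS, and -0.75 and -1.43 in BJ, where the untreated means were -0.33 and -0.46.

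In the arrays labelled HepG2, irradiated against untreated, CENPE was the single gene called, at 6 h (-0.71, SE 0.10, adjusted p = 0.00676). The arrays labelled irradiated and untreated differed little in CDKN1A, by -0.22 (SE 0.13) at 3 h and 0.05 (SE 0.13) at 6 h, and in GDF15, by -0.25 and -0.20 (SE 0.11 each), none called. Against untreated 0 h arrays, a control added later, 0 of 45 p53 targets were called higher at 3 h and 25 at 6 h. Against untreated arrays of the same time, 0 were called at either time (0 and 11 higher adjusted over the list alone). Their list was called lower at 3 h (adjusted p = 0.0149) and higher at 6 h (5.19e-07), but with an estimated correlation adjusted p was 0.834 and 0.376, and at 3 h it was 0.0955 and 0.0849 without replicate 2 or 3. Genes of G2 and mitosis were called higher at 3 h (4.55e-06) with 0 members called, 0 adjusted over the list alone, and lower at 6 h (1.03e-05) with 1 member called (8 lower and 2 higher adjusted over the list alone). With an estimated correlation their adjusted p was 0.068 and 0.0765. At 3 h limma called 0 genes, with 809 at an unadjusted p under 0.05, and at 6 h 917 were under that value. With the replicate number as a block 56 genes were called at 6 h, where the numbers paired the arrays. Leaving out replicate 1 of every group gave 939 genes at 3 h and 372 at 6 h, and leaving out a single array gave 2 at 3 h (irradiated replicate 1) and 12 at 6 h (untreated replicate 1). At 6 h, 0 genes were called without irradiated replicate 1 or 3, untreated replicate 2, or all arrays of replicate 2 or 3.

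In the arrays labelled G361 limma called 0 genes at either time, with 106 and 226 at an unadjusted p under 0.05. CDKN1A was at -0.74 (SE 0.47) at 3 h and -0.26 (SE 0.47) at 6 h, and GDF15 at -0.40 and -0.39 (SE 0.29 each). Among the 3 arrays labelled untreated at 6 h the standard deviation of CDKN1A was 1.22 log2, against 0.134 or less in the same group of the other lines. The p53 list was called lower at 3 h (adjusted p = 4.22e-11, but 0.203 with an estimated correlation, and 0.409 without replicate 3) and not called at 6 h (0.163, or 0.00197 without replicate 1). Genes of G2 and mitosis were called higher at 3 h (2.09e-10) and lower at 6 h (9.91e-17), but with an estimated correlation adjusted p was 0.372 and 0.203, and at 3 h it was 0.648 without replicate 3. In both lists 0 members were called at either time, 0 adjusted over the list alone. With the replicate number as a block 0 genes were called at 3 h and 1 at 6 h, and 1 also without irradiated replicate 1.

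The other 9 lists were tested in 90 combinations of line and time. Camera called 28, 8 higher and 20 lower, and NF-kB targets in U2OS at 3 h were the single one that held with an estimated correlation, where adjusted p was 0.0316 to 0.878 for the 28. Outside TK6, DNA replication genes were called higher in U2OS at 3 h and lower in G361, HepG2 and BJ at both times. In G361 the other calls, all lower, were the lists of repair, immediate early and heat shock genes at both times and the stress response at 3 h. Repair genes were also called lower in HepG2 at 3 h, and in BJ at 6 h repair and interferon-stimulated genes were called lower and histone and stress response genes higher. In U2OS histone genes were called lower and NF-kB targets higher at both times. The list of cholesterol synthesis was called at neither time in any line.

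**Figure D4:**
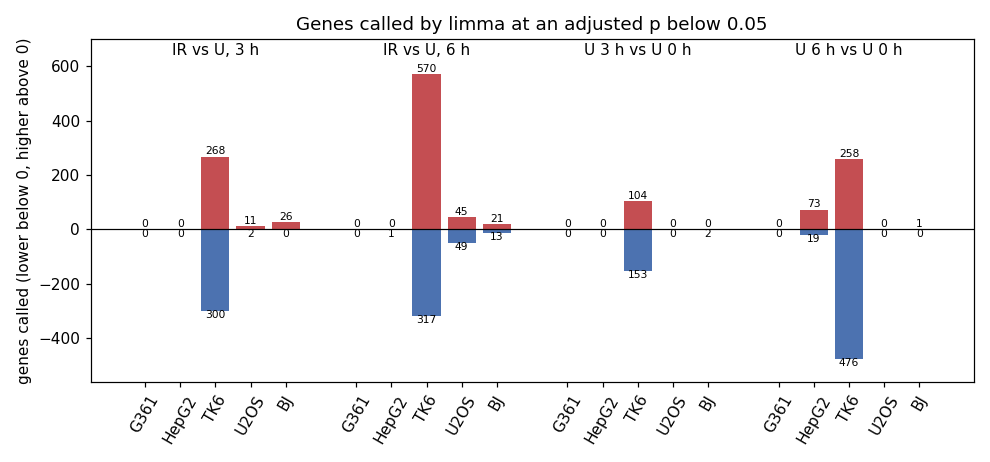
Number of genes called higher (upward bars) and lower (downward bars), per line and time. Bars on the left compare irradiated with untreated arrays of the same time. Those on the right compare untreated arrays at 3 h and 6 h with untreated arrays at 0 h. In irradiated against untreated arrays, TK6 had 568 and 887 called genes at 3 h and 6 h, U2OS 13 and 94, BJ 26 and 34, HepG2 0 and 1, and G361 0 and 0.

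No gene was called in all 5 lines, and the rule for naming genes common to all lines therefore gave none. Since 0 genes were called in G361 at either time, no gene could be called in all 5. The genes called in 3 lines were chosen after their values were seen. At 3 h, 9 genes rose in TK6, U2OS and BJ: GDF15, TP53INP1, SESN1, ATF3, CDKN1A, PPM1D, SESN2, TIGAR and GADD45A. At 6 h, 9 genes rose in these lines (TP53INP1, GDF15, MDM2, DDB2, CDKN1A, FAS, ZMAT3, TIGAR and CYFIP2), and PLK1, NEK2, PSRC1, CCNB1 and KIF14 fell in the same 3 lines. CENPE fell in HepG2, TK6 and U2OS. Independent lists of the same sizes would share 3.4e-04 genes called higher at 3 h, 0.0022 called higher at 6 h and 0.00117 called lower at 6 h among the 12970 genes tested in every line. Between times within a line, 230 genes rose at both times in TK6 and 76 fell at both (10.7 and 6.68 for independent lists), and 11 rose at both times in each of U2OS and BJ. Across genes, which are not independent replicates, the changes of TK6 and U2OS correlated at 0.20 (3 h) and 0.35 (6 h), those of TK6 and BJ at 0.24 and 0.21, and those of G361 and TK6 at -0.14 and 0.11.

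**Figure D5:**
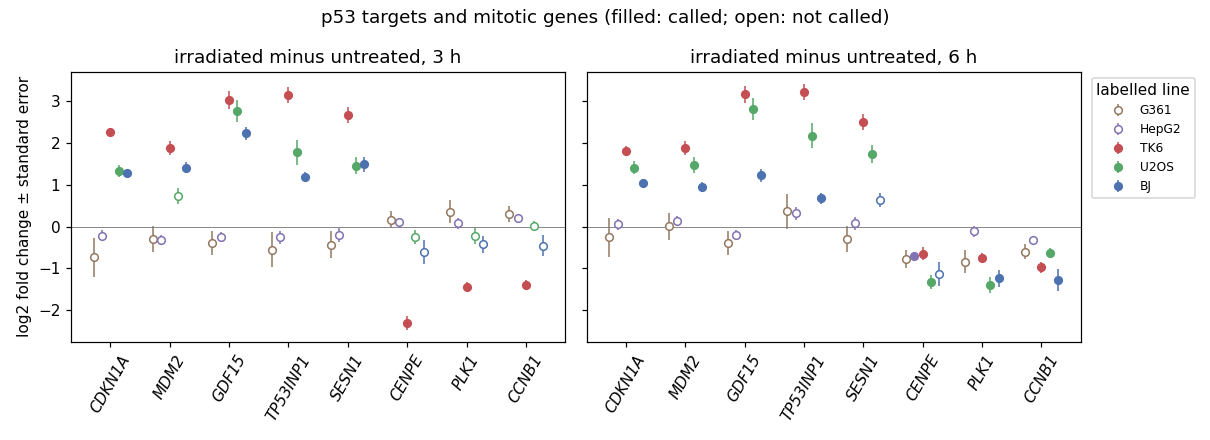
Log2 change of named genes in irradiated against untreated arrays of the same time (vertical axis, with standard errors) in the 5 lines. GDF15 rose by 3.02, 2.76 and 2.23 at 3 h in TK6, U2OS and BJ and stood at -0.40 and -0.25 in the arrays labelled G361 and HepG2.

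The change after irradiation differed between the lines for 214 of 16027 genes at 3 h and 293 at 6 h, by a moderated F test over all 75 arrays. At 3 h the smallest adjusted p was that of GDF15 (F = 52.1, adjusted p = 5.05e-15), whose change ranged from -0.40 in G361 to 3.02 in TK6. Then came PSRC1, FUCA1, the damage recognition gene XPC, SESN1, TP53INP1, TP53I3, DUSP14, ANKRD20A12P and ZNF697. FUCA1 was at 3.67 in TK6, 0.36 in U2OS and 0.12 in BJ, and TP53I3 at 2.23, 0.15 and -0.04. At 6 h the first was TP53I3 (adjusted p = 1.73e-15), at 3.50 in TK6 and between 0.23 and 0.59 in the other lines, followed by FUCA1, GDF15, CYP4F3, TNFSF4, LCE1B, GASK1B, ZNF697, PXT1 and CEACAM1. With the replicate number within each line as a block the counts were 441 and 656, and without replicates 2 or 3 of every group they were 64 and 52 at 3 h and 81 and 91 at 6 h.

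The untreated controls also moved with time. In TK6 at 6 h against 0 h, the zinc exporter gene SLC30A1 fell by 2.28 log2 (SE 0.14, adjusted p = 4.39e-08), with RBM4 (-2.12), PFKFB4 (-1.83) and TNFRSF10D (-1.55) behind it. The chemokine gene CXCL10 (1.75, SE 0.25, adjusted p = 6.71e-04), ANKRD37 (1.598), FAM200C (1.35) and TLCD1 (1.32) rose. In total 258 genes rose and 476 fell at 6 h, 734 together or 1831 with the replicate number as a block, and 104 rose and 153 fell at 3 h. Without single arrays these totals ranged from 281 (without 0 h replicate 2) to 659 and from 51 (without 0 h replicate 3) to 385. In the arrays labelled HepG2, 73 genes rose and 19 fell between 0 h and 6 h, where the median of all genes stood at 0.06, and 55 rose and 47 fell after quantile normalization, where it was 0.003. TP53INP1 (2.03), FUCA1 (1.995), GDF15 (1.99, SE 0.11, adjusted p = 1.68e-09) and ATF3 (1.90) rose most, and BORA (-1.48), PIF1 (-1.18), FAM83D (-1.003) and ID2 (-0.91) fell most. Of 45 p53 targets 15 rose there (27 adjusted over the list alone), CDKN1A by 1.32 and MDM2 by 1.05, with adjusted p = 4.58e-28 for the list but 0.0628 with an estimated correlation. Of the genes of G2 and mitosis 5 fell (list adjusted p = 7.19e-11, and 0.0277 with an estimated correlation). The count of 92 was 257 without 0 h replicate 2 and 39 to 55 without 0 h replicate 3 or any of the arrays at 6 h, and at 3 h, where 0 genes were called (1490 at an unadjusted p under 0.05), it was 24 with the replicate number as a block and 35 without 0 h replicate 2.

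In untreated BJ, the sphingosine receptor gene S1PR3 was called at 6 h (0.75, SE 0.09, adjusted p = 0.00422), but 0 genes without 6 h replicate 2 or 0 h replicate 2, and 2 without 6 h replicate 3. At 3 h CHAC1 fell by 1.498 (SE 0.16, adjusted p = 3.52e-04) and SESN2 by 1.09 (SE 0.10, adjusted p = 5.33e-05), both named after their values were seen, and 4 genes were called with the replicate number as a block. In untreated G361 and U2OS limma called 0 genes at either time, with 291 and 282 (G361) and 888 and 118 (U2OS) at an unadjusted p under 0.05. The median of all genes in untreated U2OS at 3 h stood at -0.13 against 0 h, and at -0.005 after quantile normalization.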

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

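Tests of exchanged array labels by p53 score, of stress in the untreated controls, of the number of genes tested and of the hepatocyte markers were chosen after the result they bear on was seen.

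GDF15, PSRC1, FUCA1 and TP53I3 headed the genes whose change after irradiation differed between the 5 lines, 214 at 3 h and 293 at 6 h. When the labels irradiated and untreated were drawn anew within each line and time, 9 of 100 splits gave as many genes at 3 h (highest other 419) and 5 of 100 at 6 h (highest other 408), the real one included at both times. In 7 of the other 8 at 3 h and in all other 4 at 6 h, most labels of at least 1 line were exchanged. Such an exchange carries the irradiation effect over and itself sets lines apart. It occurred in 95 of all 100 draws at each time, so it does not mark out the large splits. By the share set beforehand, chance was not excluded at either time. Since nearly all draws carry an irradiation effect over, they do not decide whether chance gives such counts. In TK6, 42 genes such as AURKA and CENPE differed between the 2 times, and 10 of 100 splits gave as many, the real one included (highest other 535). In the other 9, at least 2 of the 3 irradiated arrays of a time were exchanged for untreated ones, which tends to add the effects of the 2 times instead of subtracting them, so these splits do not decide about chance either.

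The p53 and mitotic lists differed in single lines from the mean of the other 4, tested as a difference with an estimated correlation. The p53 targets lay below the other lines in G361 by -0.7638 log2 at 3 h (adjusted p = 4.84e-08) and -0.6705 at 6 h (2.3e-06), and in HepG2 by -0.6262 (2.84e-05) and -0.4851 (1.86e-04). They lay above in TK6 by 1.001 (1.59e-06) and 0.9064 (2.84e-05), and in U2OS at 6 h by 0.4236 (0.00421). Genes of G2 and mitosis lay above the other lines in G361 at 3 h by 0.5879 (0.00206) and in HepG2 by 0.4354 (0.0307) and 0.5155 (0.0122). They lay below in TK6 at 3 h by -0.9447 (0.00206) and in BJ at 6 h by -0.5883 (0.00769). Each mean of the other lines for TK6, U2OS and BJ includes G361 and HepG2. At 6 h the mean p53 effects were 0.03 in G361, 0.18 in HepG2, 1.29 in TK6, 0.91 in U2OS and 0.43 in BJ, so the excess of U2OS rests on G361 and HepG2.

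These differences depend on which arrays of G361 and HepG2 were labelled untreated. In TK6, U2OS and BJ the highest untreated p53 score was 0.154 and the lowest irradiated 0.371 log2 above 0 h, and the middle, 0.262, parted them. In each of G361 and HepG2, 3 arrays labelled untreated lay above that value and 3 labelled irradiated below it, with equal numbers in 6 of 6 replicate sets. Exchanged labels within replicate sets are a candidate explanation, which this count cannot support, since it restates the pattern that prompted the test. A test written beforehand used other genes. Across genes outside the p53 list, the changes from 0 h of HepG2 arrays labelled untreated 6 h and irradiated 3 h were correlated with those of irradiated 3 h and untreated 6 h arrays of TK6, U2OS and BJ. In 5 of 6 comparisons the higher correlation was with the other label, with the HepG2 arrays labelled untreated 6 h against U2OS as the exception (0.107 and 0.197). No correlation was above 0.197, and for HepG2 arrays labelled irradiated 3 h against BJ the higher was -0.021. The 6 comparisons share the HepG2 arrays, so they are not separate tests, and G361 was not compared. The genes used include those of mitosis, so the comparisons do not part exchanged labels from p53 activity of another origin. The score of G2 and mitosis, relative to 0 h, also went the way an exchange needs. In HepG2 it was -0.19 to -0.16 in the arrays labelled untreated 6 h and 0.33 to 0.37 in those labelled irradiated 3 h. In G361 it was -0.35, -0.33 and -0.20 in the 3 arrays labelled untreated with high p53 scores, 0.16 in untreated 6 h replicate 3 and 0.18 to 0.33 in those labelled irradiated 3 h. Mitotic genes also fell where p53 targets rose in TK6, U2OS and BJ. In untreated BJ their score stood at -0.33 (SD 0.40) at 3 h and -0.46 (SD 0.30) at 6 h, with no mitotic gene called. The mitotic scores of HepG2 and G361 therefore do not part exchanged labels from p53 activity of another origin, and the exchange stays open. Stress in the untreated controls alone needs arrays labelled irradiated at 3 h to rise as elsewhere. Their highest rise over 0 h was 0.0633 in HepG2, or 0.3229 with 2 standard errors added. The smallest rise of the other lines was 0.406, in BJ. The low scores of these arrays are part of the pattern that prompted the test, so it restates that pattern. With 3 against 3 arrays, 2 standard errors are also a loose limit. The test therefore does not decide about stress in the controls. A weaker p53 response in these lines was not tested apart from the labels, and no array was moved to another group.

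Hepatocyte markers were near the level of the other lines in the arrays labelled HepG2. The choice of probe set is argued against, since 0 of 11 markers had any probe set at least 1 log2 above every other line. An exchange of line labels within the series is argued against too, since at most 1 of 11 markers stood that high in another line (SERPINA1 in U2OS). Degraded RNA or failed arrays would leave few genes specific to the line, and 41 genes stood at least 3 log2 above every other line, against 94 in G361, 172 in TK6, 71 in U2OS and 159 in BJ. The value of 41, below the next lowest, 71, divided by 1.5, went the way that these explanations need. Tests of either part were added after it had been seen. For degraded RNA, the 5' minus 3' GAPDH control was -0.006 log2 there, 0.058 in TK6, 0.0356 in BJ, -0.074 in U2OS and -0.269 in G361, whose own markers were all highest. The G361 value rests on its 5 replicate 1 arrays (-0.937 to -0.678), and without replicate 1 it was 0.00395 against -0.0207 in the arrays labelled HepG2, so these means alone do not decide. Those 5 arrays nevertheless kept their melanocyte markers, at a mean of 10.68 against 10.84 in the other G361 arrays (difference -0.1516), while the control was far higher, -0.065 to 0.0444, in every array labelled HepG2. A loss of 5' signal larger than any in the arrays labelled HepG2 thus left lineage markers high, which argues against degraded RNA as the whole cause. For failed arrays, the median residual SD between arrays was 0.1758 there, the lowest of the 5 lines. Its moderated form was 0.1837, against 0.1831 in BJ, so the rank depends on the measure. With COL6A3 at 11.3 and RUNX2 at 9.17 in these arrays, the values argue against failed arrays. The hepatocyte list had a mean of 3.75 log2 in the arrays labelled HepG2, with only AFP highest there. These levels go the way that cells other than HepG2 from outside the series need. No reference profile was compared, so that explanation was not tested and stays open.

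More genes were called in TK6 than in the other lines. The median residual SD between arrays was 0.1958 in TK6, above 0.1758 in HepG2 and 0.1795 in BJ. This argues against a smaller spread as the cause of the higher counts relative to HepG2 and BJ. It was below 0.2104 in G361 and 0.2557 in U2OS, the largest. A smaller spread was also tested by giving TK6 the variances of U2OS. Over the 13515 genes tested in both lines, 226 and 251 calls were left at 3 h and 6 h. With its own variances TK6 had 568 and 887 over all its genes, so many calls depended on the spread. The 477 calls at both times together stood against 103 in U2OS over the same genes, which argues against spread as the whole cause. Variances of the other lines were not tried. The number of genes tested in TK6 was at most 0.9901 of that in another line, which argues against it as the cause. In U2OS at 3 h, leaving out the untreated array with the compressed range gave 18 genes against 13, within the 1.5 times set beforehand, which argues against that array alone as the cause. It was the highest of the 6 single arrays left out (the others gave 8 to 13), and quantile normalization gave 28 and leaving out replicate 1 of every group 37, so a part of the array in the low count stays open. The label exchange described above stays open for G361 and HepG2, and a biological difference between TK6 and the other lines was not tested.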

How the results depend on the processing

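Untreated 0 h arrays as the control, and all arrays of 1 replicate number left out, were tests chosen after the data had been seen.

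GDF15, CDKN1A, FUCA1, PSRC1 and the other genes named as called in the report made 197 results. They were run without the level filter, with quantile normalization, the replicate block, the mean of all probe sets, 1 array left out and, for irradiated against untreated arrays, the 6 compared arrays alone, and 120 were called under each of these that was run. Single genes were not run in the fit of 75 arrays, against 0 h or without a replicate number. The other 77 were lost under at least 1, among them 66 with 1 array left out, 28 with the mean of all probe sets and 19 with the 6 compared arrays alone. With the replicate block 0 were lost, and 0 were reversed under the alternatives run on them. Without the level filter no count moved by over 1.5 times and no call of the p53 or mitotic lists changed.

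Quantile normalization of the 15 arrays gave 1 gene in G361 at 6 h, 12 in HepG2 at 6 h, 1 in the HepG2 difference between times, 28 in U2OS at 3 h and 53 in BJ at 6 h, where the values as deposited gave 0, 1, 0, 13 and 34. It changed the share called higher from 84.6% to 46.4% in U2OS at 3 h, from 61.8% to 47.2% in BJ at 6 h and from 79.3% to 53.9% in untreated HepG2 at 6 h. It also took the p53 list of HepG2 at 3 h to an adjusted p of 0.051. The cause was not tested. The mean of all probe sets gave 6 genes in HepG2 at 6 h.

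One fit of all 75 arrays, which shares 1 spread among the lines, gave 4 genes in HepG2 at 6 h, 76 and 206 in U2OS, 148 (20 of them higher) in BJ at 6 h, and 7 and 2 in the time differences of U2OS and BJ. A fit of the 6 compared arrays alone, with fewer degrees of freedom, gave 6 genes in HepG2 at 6 h, 2 in U2OS at 3 h and 105 (22 higher) in BJ at 6 h, against 21 higher of 34. Untreated 0 h arrays as the control gave 65 and 221 genes in HepG2, 1494 and 2027 in TK6, and 43 and 301 in BJ at 3 h and 6 h. The p53 targets called higher than at 0 h numbered 0 and 25 in the arrays labelled HepG2 at 3 h and 6 h. In TK6 they numbered 34 and 35, in U2OS 7 and 22, in BJ 11 and 19, and in G361 0 at both times. This control adds the change of untreated cells over time to that after irradiation.

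The replicate block gave 1 gene in G361 at 6 h, 6 and 56 in HepG2 at 3 h and 6 h, 1203 and 1868 in TK6, 36 and 157 in U2OS and 75 in BJ at 6 h. All genes called without it were called with it, in the same direction, in every comparison of irradiated with untreated arrays. In untreated cells it gave 24 and 306 genes in HepG2 at 3 h and 6 h, 995 and 1831 in TK6, and 4 and 6 in BJ. For the difference between times it gave 2 genes in HepG2, 146 in TK6 and 1 in U2OS, and for differences between lines 441 at 3 h and 656 at 6 h.

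Camera with an estimated correlation ended 10 calls of the p53 and mitotic lists. In G361 the adjusted p was 0.203 for p53 targets at 3 h, and 0.372 and 0.203 for mitotic genes at 3 h and 6 h. In HepG2 it was 0.834 and 0.376 for p53 targets and 0.068 and 0.0765 for mitotic genes, in U2OS 0.203 for mitotic genes at 3 h, and in BJ 0.261 and 0.0674 for mitotic genes. Fry ended 8 of these 10. It gave 0.617 for p53 targets of G361 at 3 h, 0.7 and 0.508 for its mitotic genes, 0.779 and 0.371 for p53 targets of HepG2, 0.068 for its mitotic genes at 3 h, and 0.393 and 0.508 for mitotic genes of U2OS and BJ at 3 h. The p53 lists of TK6, U2OS and BJ kept their calls under both at both times. Of the other 9 lists, 27 calls ended with an estimated correlation and 22 with fry.

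Leaving out arrays, singly or by replicate number, moved many counts, with fewer samples in each fit. The ranges at 3 h and 6 h were 211 to 558 and 246 to 823 genes in TK6 (lowest without replicate 3 at both times), 2 to 37 and 12 to 256 in U2OS (lowest without replicate 3, highest without replicate 1), and 12 to 22 and 0 to 20 in BJ (lowest without replicate 3). In HepG2 they were 0 to 939 and 0 to 372, highest without replicate 1, and in G361 at 6 h 0 to 1, highest without irradiated replicate 1. In untreated cells they were 51 to 385 and 281 to 659 in TK6 (lowest without 0 h replicate 3 and 0 h replicate 2), 0 to 35 and 39 to 257 in HepG2 (highest without 0 h replicate 2, lowest at 6 h without 6 h replicate 2), and 0 to 2 in BJ at 6 h (0 without 6 h replicate 2 or 0 h replicate 2, 2 without 6 h replicate 3). The difference between times in TK6 gave 17 to 46 genes, lowest without untreated 6 h replicate 2, and the differences between lines 52 to 252 at 3 h (lowest without replicate 3) and 81 to 317 at 6 h (lowest without replicate 2).

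The p53 and mitotic lists of G361 at 3 h lost their calls without replicate 3. Without a replicate number, adjusted p ranged from 6.44e-14 to 0.409 for p53 targets, from 1.49e-14 to 0.648 for mitotic genes and from 6.3e-04 to 0.896 for immediate early genes, each highest without replicate 3, where the immediate early genes changed direction. Of the other lists called there, DNA replication kept its call without any replicate number, repair, heat shock and immediate early genes lost it without replicate 1 or 3, and the stress response without replicate 3. For p53 targets it ranged from 0.00197 (without replicate 1) to 0.571 in G361 at 6 h and from 0.00157 to 0.0955 (without replicate 2) in HepG2 at 3 h, where it was 0.0849 without replicate 3. Calls of the p53 and mitotic lists in TK6, U2OS and BJ held in every one of these.

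Signal over background limits genes of low level. On simulated data, drawn independently for each gene and array, a change of 1 log2 was recovered in 59.7% to 91.0% of genes. One of 0.5 log2 was recovered in 1.49% to 41.8% over the 10 comparisons, and both were lowest for U2OS at 6 h. Small changes may therefore be missing from the low counts such as 13 in U2OS at 3 h, where the replicate block gave 36.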

Other observations

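All splits of the arrays were tests planned before the result was seen, and the lists below come from the planned set, but which of them to describe was chosen after their values were seen.

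In BJ at 6 h, genes of DNA replication lay -0.60 log2 below the mean of the other 4 lines (adjusted p = 0.00934 with an estimated correlation) and replication-dependent histone genes 0.20 above it (0.0368). In TK6 at 6 h the histone genes lay -0.30 below the other lines (0.00934). CCNE2 was the replication gene called in BJ, and H2AC6 was called in opposite directions, higher in BJ (0.66) and lower in TK6 (-1.09) and U2OS (-0.86). NF-kB targets in U2OS at 3 h, higher within that line, had an adjusted p of 0.211 for the difference from the other lines.

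Untreated cells moved several lists with time. Immediate early genes were lower in TK6 at 3 h and 6 h against 0 h (adjusted p = 0.0277 and 0.0335 with an estimated correlation), with FOSB at -1.50 and KLF6 at -0.94 at 6 h, while MYC rose by 0.76. Heat shock genes such as HSPH1 (0.40) and DNAJB1 (0.48) were higher there at 6 h (0.0277). Genes of G2 and mitosis in untreated HepG2 were higher at 3 h (0.00968), with 0 members called and 29 adjusted over the list alone. Cholesterol synthesis genes of TK6, among them SC5D (-1.01) and IDI1 (-0.82) at 6 h, had 6 members called at 6 h, but the list had an adjusted p of 0.295 with an estimated correlation.

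The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. The real count and the highest of the other splits were 568 and 0 in TK6 at 3 h, 887 and 0 at 6 h, 13 and 0 in U2OS at 3 h, 94 and 0 at 6 h, and 34 and 0 in BJ at 6 h, with 1 of 10 splits as large, the real one. In BJ at 3 h the real count was 26 and 2 of 10 splits were as large. The other, irradiated replicates 1 and 3 with untreated replicate 1 against the rest, gave 196, which points to a structure of the samples apart from irradiation. It keeps the arrays of replicate 1 together and those of replicate 2 together, and parts those of replicate 3. It also parts the 3 arrays with the lowest mitotic scores relative to 0 h (-1.14, -0.98 and -0.78) from the rest (-0.21 to 0.01). The splits that part all 3 replicate numbers as the real one does gave 0 at most. In HepG2 at 6 h the real count was 1 and another split, which keeps replicate 1 together, gave 1, so 2 of 10 were as large, while the splits that part all 3 numbers gave 0. For untreated arrays the numbers were 257 and 0 (TK6 at 3 h), 734 and 0 (TK6 at 6 h), 92 and 1 (HepG2 at 6 h), 2 and 0 (BJ at 3 h) and 1 and 0 (BJ at 6 h), with 1 of 10 as large. Where limma called 0 genes, in G361 throughout, HepG2 at 3 h, untreated HepG2 at 3 h and untreated U2OS, 10 of 10 splits gave as many (unadjusted counts are in the report).

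For the difference between times, 100 of 100 drawn splits gave as many genes as the 0 of limma in G361, HepG2, U2OS and BJ, with highest others of 0, 119, 101 and 393 (102, 329, 371 and 302 genes at an unadjusted p under 0.05). No gene was called in all 5 lines at 3 h or 6 h, and 100 of 100 splits gave as many. Every split of the arrays of G361 called 0 genes at both times. The count over all 5 lines therefore had to be 0 in each draw and decides nothing about chance. Genes called the same way in at least 3 lines, such as GDF15, CDKN1A and PLK1, numbered 9 at 3 h and 15 at 6 h. The real split was the 1 of 100 as large, and the highest other was 0 at both times. Every other split of the arrays of TK6 or of U2OS called 0 genes at both times. Nearly every draw therefore had to give 0, so these draws do not decide about chance.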
